A study of Mus musculus with 30 samples.

How the data were processed

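The 30 samples were mouse V6.5 embryonic stem cells (ESCs), wild type (WT) or lacking Tet1, Tet2 and Tet3 (TKO), and a TKO culture grown together with WT cells for 3 days (TKOmix). There were 8 H3K27ac chromatin samples treated with bisulfite (days 2 and 5 of retinoic acid, RA, WT and TKO, 2 each). There were 3 H3K27me3 and 3 H3K4me3 chromatin samples of ESCs (WT, TKO and TKOmix, 1 each), 2 bulk RNA samples of ESCs (WT and TKO, 1 each) and 14 single-cell RNA libraries. The single-cell groups were RA day 2 WT and TKO, RA day 5 WT, TKO and TKOmix, and extraembryonic endoderm (XEN) differentiation WT and TKO, 2 libraries each. The labels do not say whether the mixed cells were sorted before sequencing, nor whether replicates are separate cultures, so each p measures the spread between samples, which may be technical.

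Of each H3K27ac sample the authors deposited methylated and unmethylated cytosine counts per 200 bp bin, read counts per 200 bp bin, and peaks with a score. Which column holds the methylated calls was settled from the values, low at promoters and high elsewhere, and the cytosine context is not given in the sources used here. The score deposited with the peaks is that of the authors' peak caller, whose scaling is not given in the sources used here, and it served only to choose a stricter set of 88162 regions. For the ESC marks the authors deposited read counts in 200 bp bins within 10 kb of each transcription start site (TSS). A read can count in more than 1 bin. The bins end at the chromosome lengths of build mm9, and coordinates below are 1-based in mm9. The tools bcl2fastq, Bismark, Bowtie, HOMER and bedtools and the builds mm9 and mm10 are named, without versions, per the submitters' processing notes. The deposited single-cell values are expected counts per gene and cell from RSEM on GRCm38 with Ensembl genes, per the file names. Whether molecular identifiers were collapsed is not given in the sources used here. The deposited bulk values are expected counts, TPM and FPKM from RSEM with the build written as mm38, per the file headers. The FPKM was not used here.

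Single-cell expected counts were summed per library and rounded after summing. Cells with at least 1000 counts were kept, which left out 0 to 6 cells of a library. A limit of 20% mitochondrial counts left out 0 cells, as mitochondrial genes held 0% of the counts. No doublet caller was run. Of 55364 gene IDs, 55104 matched a symbol. Libraries were compared with edgeR 4.0.16, by its two-sided quasi-likelihood test with TMM scaling, filterByExpr and robust spread, and with Benjamini-Hochberg adjustment over all tested genes at 0.05. The RA comparisons came from 1 model of the 10 RA libraries (5 residual degrees of freedom, prior 20, biological coefficient of variation 0.214). XEN came from its 4 libraries (2 residual, prior 14.1, 0.22). A 2 against 2 permutation cannot give a two-sided p under 0.333. Where a group held no counts, its fold is printed as a lower limit that takes 3 counts over the group's 2 libraries. With 1 to 3 counts a ratio and its counting interval are printed. Intervals cover counting error only.

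The 21 gene lists were written before the data were examined. They are TET enzymes, DNA methylation machinery, PRC2 and H3K27 demethylases, pluripotency, epiblast, retinoic acid response, Hox, extraembryonic endoderm, neural, mesoderm, neural crest, trophoblast, 2-cell-like, germline, imprinted, mesenchyme, blood and endothelium, Wnt targets, p53 targets, stress and cell cycle. Lists with at least 5 measured members were tested with camera of limma 3.58.1 at its preset correlation of 0.01, two-sided, Benjamini-Hochberg over the lists of 1 comparison. The same test with the correlation estimated per list, and fry, were alternatives. Named genes followed a rule fixed in advance. Tet1 to Tet3 were always named. A comparison named up to 6 rising and 6 falling genes by largest fold among those past the test, with a mean of 50 CPM (counts scaled to library size) in the higher group and replicates that did not overlap. Each list named up to 4 members by smallest p, or the 2 with the highest CPM where none passed. Of comparisons with 1 library per group, up to 6 higher and 6 lower items were named among genes with at least 100 counts or the 6519 promoters with most signal, with list members at a log2 ratio of 1 or more. Genes named outside the rule are marked. 1 gene that the rule would name is counted in its list and is not reported here by name.

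Cells were grouped with scanpy 1.11.5 and leidenalg 0.10.2 (2000 variable genes, 30 components, 15 neighbours, resolution 0.6), RA and XEN apart. A cluster took a class name where at least 3 marker genes of a class, from lists fixed in advance, were at least 2-fold higher than in the other cells. Shares carry 95% Wilson intervals.

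The H3K27ac peaks of the 8 libraries were merged to 201405 regions (median 936 bp), of which 22909 were found in all 8 libraries. Bin reads were assigned by bin midpoint, and regions were compared with edgeR as above in 1 model of 8 libraries (4 residual degrees of freedom, biological coefficient of variation 0.216). Replicates shared 63.9 to 74.1% of peaks by 1 bp, and 39.5 to 44.2% by 50% reciprocal overlap. Methylation was tested per region with at least 10 calls in every library compared, by a quasi-binomial model with spread moderated by limma's squeezeVar, two-sided, and Benjamini-Hochberg adjusted. TSS positions came from the authors' H3K4me3 promoter file. A region was assigned to a gene within 10 kb of its TSS.

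For the ESC marks, reads within 2 kb (H3K27me3) or 1 kb (H3K4me3) of 26074 TSSs were scaled by library total and compared as log2 ratios. Bulk genes with at least 100 counts over the pair were compared as the log2 ratio of CPM with a pseudocount of 1. With 1 library per group these comparisons carry no p, no test and no replicate check, and the printed standard errors are counting errors. The percentile of a list is its place among 10000 random lists of like signal. Genes near changed promoters or changed regions were taken as sets into camera on the expression data.

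Each test was checked on simulated data. For single cells on day 2, day 5 and XEN, 83.3%, 81.8% and 92.4% of 8-fold changes were recovered (66 genes). For 4-fold changes these were 47.8%, 52.2% and 56.7% (67 genes), and for 2-fold changes 1.5%, 3.0% and 7.5% (67 genes). For H3K27ac, 93.9% of 8-fold changes were recovered on each day (66 of 201404 regions). Of 4-fold changes 47.8% and 40.3% were recovered, and of 2-fold changes none (67 regions each). The single-cell and H3K27ac simulations used a larger spread between libraries than was fitted to the data, so recovery in the data may be higher. For methylation on days 2 and 5, with 20000 changed regions, 75.1% and 71.3% of differences of 40 points were recovered, 19.8% and 17.6% of 20 points, and 3.2% and 3.3% of 10 points. With 200 changed regions 3% and 16.7% of differences of 40 points were recovered. Of all calls there 3 of 5 and 4 of 17 were false, against 271 of 6809 and 380 of 6525 with 20000 changed regions. Recovery depended on how many regions changed, so the shares do not carry over to comparisons with many more calls than were simulated.

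Alternatives were RLE scaling, DESeq2 1.42.0, other filters, a replicate block, leaving out each library in turn, other clusterings, other region sets, other call minimums, limma on the methylation level, other windows and pseudocounts, TMM and TPM, and other sizes of gene sets. Chosen after the data were seen were thinned XEN libraries, the fit without the deepest cell (218798 counts, 14.71% of day 2 TKO library 1), the fit without TKOmix, clustering without listed genes, gene sets tested against all genes, and the interaction of H3K27ac. The analysis used R 4.3.3, Python 3.11.15, statmod 1.5.0, data.table (1.17.8), igraph 0.11.9, bedtools 2.31.1, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.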

Results

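The study asks how far the TET enzymes act in early differentiation through H3K27me3 and how far through DNA methylation. The data cover 8 H3K27ac bisulfite libraries, 3 H3K27me3, 3 H3K4me3, 2 bulk RNA and 14 single-cell RNA libraries, with 2 libraries in each H3K27ac and single-cell group and 1 in each other group. RA was given at 1 µM, and XEN differentiation ran 9 days with activin A at 10 ng/mL and RA at 0.1 µM. Total counts per single-cell library were 1294194 and 734026 (day 2 WT), 1487696 and 635890 (day 2 TKO), 2023087 and 954761 (day 5 WT), 1747341 and 1606171 (day 5 TKO), and 6263665 and 4993855 (day 5 TKOmix). They were 2072135 and 2943108 (XEN WT) and 10467238 and 3584400 (XEN TKO). In library order, these held 243 and 164, 309 and 162, 307 and 214, 268 and 253, 857 and 735, 329 and 424, and 479 and 285 cells. H3K27ac bin reads were 154847197 and 129589226 (day 2 WT), 112934715 and 111505289 (day 2 TKO), 144741247 and 120133680 (day 5 WT), and 136411258 and 138824568 (day 5 TKO). Methylation calls in the same order were 89075465 and 71788477, 61125624 and 70111050, 77438358 and 66759069, and 87101793 and 88415843. H3K27me3 bin reads were 16497240 (WT), 16273297 (TKO) and 12953789 (TKOmix). H3K4me3 bin reads were 75956808, 72402520 and 50676908. The bulk RNA libraries held 18268792 (WT) and 15055998 (TKO) counts.

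Transcripts of the deleted genes remained in TKO cells. The sources used here do not say which exons were deleted, so transcript levels outside a deletion check nothing about the labels. Tet1 stood at 363 and 371 CPM in the day 2 WT libraries and 219 and 230 in TKO, at 218 and 258 against 263 and 202 on day 5, at 22 and 22.3 in TKOmix, and at 132 and 136 against 92.9 and 89.9 in XEN. Tet2 stood at 49.9 and 72 against 41.9 and 32.3 on day 2, at 25.1 and 39.5 against 31.2 and 28.8 on day 5, at 21.3 and 25.0 in TKOmix, and at 10.9 and 25.3 against 27.2 and 25.5 in XEN. Tet3 stood at 8.61 and 4.32 against 2.56 and 4.85 on day 2, at 39.9 and 40.5 against 14.7 and 17.4 on day 5, at 22 and 19 in TKOmix, and at 60.8 and 62.2 against 16.8 and 10.7 in XEN. Tet3 fell in XEN TKO cells (log2 −2.12 ± 0.30, adjusted p 9.17e-05 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 2 against 2 libraries). It fell on day 5 (−1.32 ± 0.34, adjusted p 0.0268), a call lost with any 1 of the 4 day 5 libraries left out (−1.21 to −1.44). In ESCs with 1 library per genotype, Tet1 went from 444 to 177 CPM, Tet2 from 120 to 38.7 and Tet3 from 11.3 to 6.91.

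On day 2 of RA, TKO cells held less RNA of some basement membrane and endoderm genes than WT cells, and the comparison asks what TET loss does at the start of differentiation. Mid1, a ubiquitin ligase of microtubules, fell from 301 ± 24.8 to 38.5 ± 9.67 CPM (log2 −3.00 ± 0.28, adjusted p 7.27e-07, 2 against 2 libraries, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). Pgm2l1, which makes a sugar bisphosphate, rose from 176 ± 24.4 to 1059 ± 436 CPM (2.60 ± 0.30, adjusted p 2.41e-05). Smtnl1 (2.98 ± 0.41, adjusted p 0.000336), the phosphatase Acp5 (2.56 ± 0.36, 0.000371) and the matricellular gene Ccn2 (2.28 ± 0.34, 0.000578) rose as well. These 5 genes kept their calls in every setting tried. Across 13898 genes 51 rose and 37 fell, 88 in all by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. The count was 27 without WT library 1, 19 without WT library 2, 22 without TKO library 1 and 227 without TKO library 2. It was 232 with no filter on low counts. The rising share was 58%, and 70.2% when only the day 2 libraries were fitted. It was 25.9% (7 rose, 20 fell) without WT library 1, 42.1% (8 and 11) without WT library 2 and 76.2% without TKO library 2, so the balance of rising and falling genes is not settled.

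Among 21 measured extraembryonic endoderm genes on day 2, 0 rose and 5 fell, or 8 when adjusted over the list alone, with a list median of −1.04. The basement membrane collagens Col4a1 (−2.95 ± 0.52, adjusted p 0.0221, edgeR quasi-likelihood test, Benjamini-Hochberg) and Col4a2 (−2.71 ± 0.47, 0.0116) fell. So did the laminin Lamb1 (−1.89 ± 0.38, 0.0148) and the endocytosis genes Cubn (−3.29 ± 0.64, 0.0251) and Dab2 (−2.54 ± 0.45, 0.0116). All 5 calls were lost without WT library 2, where the values were −2.58, −2.26, −1.29, −3.18 and −2.40. The list was lower by camera (adjusted p 2.73e-06), and this was lost with an estimated correlation (adjusted p 0.343) and by fry (adjusted p 0.051). Of 12 p53 targets 2 rose, Cdkn1a (1.44 ± 0.27, adjusted p 0.00919) and Pmaip1 (1.70 ± 0.36, 0.0232), or 5 over the list alone, and 0 fell. Both calls were lost without WT library 2 (Pmaip1 at 1.49). The p53 list was higher by camera (adjusted p 0.00013, estimated correlation adjusted p 0.113). The 8 genes of the 2-cell-like list had a median of 1.37 with 0 rising and 0 falling, over all genes and over the list alone. That list passed camera (adjusted p 0.0194) and lost it with an estimated correlation (adjusted p 0.343) and by fry (adjusted p 0.192). Zscan4f stood at 73.6 and 239 CPM (1.71, adjusted p 0.701), and its reads are uncertain among near-identical copies.

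Other lists did not pass camera on day 2. The de novo methylation cofactor Dnmt3l rose (1.45 ± 0.28, adjusted p 0.0116, edgeR quasi-likelihood test, Benjamini-Hochberg), 1 of 12 methylation genes (0 fell, list adjusted p 0.57). Tdgf1 rose (2.09 ± 0.40, 0.0116), 1 of 19 pluripotency genes, or 2 rising and 1 falling over the list alone (list 0.57). Lefty1 fell (−1.16 ± 0.27, 0.0465), 1 of 9 epiblast genes, 2 over the list alone (list 0.0808). Hoxc5 fell (−2.02 ± 0.46, 0.0398), 1 of 23 Hox genes, 2 over the list alone (list 0.0542). Phlda2 rose (1.90 ± 0.42, 0.033), 1 of 22 imprinted genes, or 2 rising and 7 falling over the list alone (list 0.248). Each of these 5 calls was lost without WT library 2 (1.46, 1.99, 1.42 for Dnmt3l, Tdgf1 and Phlda2). No member passed over all genes among 13 PRC2 genes (adjusted p 0.681), 18 RA response genes (0.496), 12 neural genes (0.32), 8 mesoderm (0.224), 10 neural crest (0.248), 8 trophoblast (0.859), 11 germline (0.0542), 11 mesenchyme (0.224), 9 Wnt (0.304), 11 stress (0.224) and 16 cell cycle genes (0.706). Over the list alone 2 germline, 2 Wnt, 1 mesoderm, 1 mesenchyme and 1 stress gene rose and 2 cell cycle genes fell. The RA-degrading enzyme Cyp26a1 stood at −0.19 and did not pass (adjusted p 0.86). Blood (2 genes) and TET genes (3) were too few to test in any RA comparison.

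By day 5 many endoderm genes were far lower in TKO than in WT cultures, and the comparison asks which lineages form without TET enzymes. Cubn fell from 71 ± 29.1 to 2.57 CPM (log2 −4.76 ± 0.59, adjusted p 0.000175, 2 against 2 libraries, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). The proteoglycan gene Srgn fell from 80.3 ± 14.4 to 3.43 ± 3.16 (−4.52 ± 0.48, adjusted p 3.62e-06), and the hypoxia factor Epas1 from 136 to 11.5 (−3.58 ± 0.35, 1.17e-06). The endoderm factor Gata4 (−3.57 ± 0.44, 4.41e-05) and Dab2 (−2.76 ± 0.36, 0.000156) fell. The carrier Ttr was at least 33.9-fold lower, with 88 counts in WT and 0 in TKO (6.8e-05). Sfn, an epithelial 14-3-3 gene, rose from 51.9 ± 14.8 to 395 ± 1.51 CPM (2.90 ± 0.43, 0.00162), Wnt6 from 35.7 ± 1.57 to 189 ± 8.78 (2.40 ± 0.29, 1.07e-05) and Col11a1 from 25.0 to 181 (2.91 ± 0.32, 3.93e-06). All of these kept their calls in every setting. In total 270 genes rose and 257 fell, 527 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. There were 148 without WT library 1, 330 without WT library 2, 299 without TKO library 1, 205 without TKO library 2, and 333 by DESeq2. Falling genes were the majority without WT library 1 (53 rose, 95 fell) and without WT library 2 (141 and 189).

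Of 21 extraembryonic endoderm genes on day 5, 0 rose and 16 fell, or 19 over the list alone, with a median of −2.76 (camera adjusted p 2.23e-21, estimated correlation adjusted p 0.0795). Of 23 Hox genes 5 rose and 0 fell, or 12 rising over the list alone, with a median of 0.96 (camera adjusted p 1.56e-05, estimated correlation 0.118). Hoxa5, which patterns the trunk, rose from 88 ± 13.9 to 281 ± 3.18 CPM (1.68 ± 0.27, adjusted p 0.000332 by edgeR quasi-likelihood test, Benjamini-Hochberg) in every setting. Hoxa4 rose (2.18 ± 0.52, 0.0142), though not without WT library 1 (2.79). Of 9 Wnt targets 2 rose, Lef1 (1.97 ± 0.48, 0.0167) and Axin2 (1.81 ± 0.43, 0.0154), or 6 over the list alone, and 0 fell (camera adjusted p 0.000191, estimated correlation 0.0795). Both were lost without TKO library 1 (1.82 and 1.48). Of 11 germline genes Ddx4 rose (2.49, 0.00401) and Rhox9 fell (−2.58, 0.00506), each lost without WT library 1 (Ddx4 at 1.76), and 2 rose and 2 fell over the list alone (camera adjusted p 0.0058, estimated correlation 0.157). The 16 cell cycle genes had a median of −0.53 with 0 rising and 0 falling (camera adjusted p 3.93e-05, estimated correlation 0.124). Of 11 mesenchyme genes 1 rose, Tagln (adjusted p 0.0185), or 4 over the list alone (camera adjusted p 0.046, estimated correlation 0.157). Of 8 2-cell-like genes 0 rose and 0 fell (camera adjusted p 3.93e-05, estimated correlation 0.157, fry 0.0577). Zscan4f, uncertain among its copies, held 157 counts in TKO and 0 in WT, at least 45.3-fold (adjusted p 0.402).

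Lists that did not pass camera on day 5 still held called genes. The RA response list had 1 rising and 2 falling of 18, or 3 and 3 over the list alone (camera adjusted p 0.412). In it Cyp26a1 fell from 528 to 129 CPM (−2.04 ± 0.30, adjusted p 0.000146, edgeR quasi-likelihood test, Benjamini-Hochberg). Pluripotency genes counted 2 rising and 5 falling of 19, or 3 and 6 over the list alone (camera 0.0817), with Dppa5a lower (−2.28, 0.000146) and Dppa4 higher (2.15, 0.000381). Methylation genes counted 1 rising and 2 falling of 12 (camera 0.084), with Dnmt3l lower (−2.71 ± 0.34, 2.1e-05). Imprinted genes counted 2 rising and 4 falling of 22, or 2 and 5 over the list alone (camera 0.121), with Plagl1 lower (−2.11, 0.000124). PRC2 genes counted 0 and 1 of 13 (camera 0.412), with Epop lower (−2.04, 0.00138; −1.76 and not called without WT library 1). Neural genes counted 2 and 0 of 12, or 3 and 0 over the list alone (0.0817), and mesoderm 1 and 1 of 8 (0.0536), with Wnt3 higher (2.28, 0.000663). Epiblast genes counted 1 and 1 of 9 (0.667), neural crest 1 and 1 of 10 (0.728), trophoblast 0 and 0 of 8 (0.728), p53 0 and 0 of 12 (0.121), and stress 1 and 1 of 11 (0.284).

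**Figure D1:**
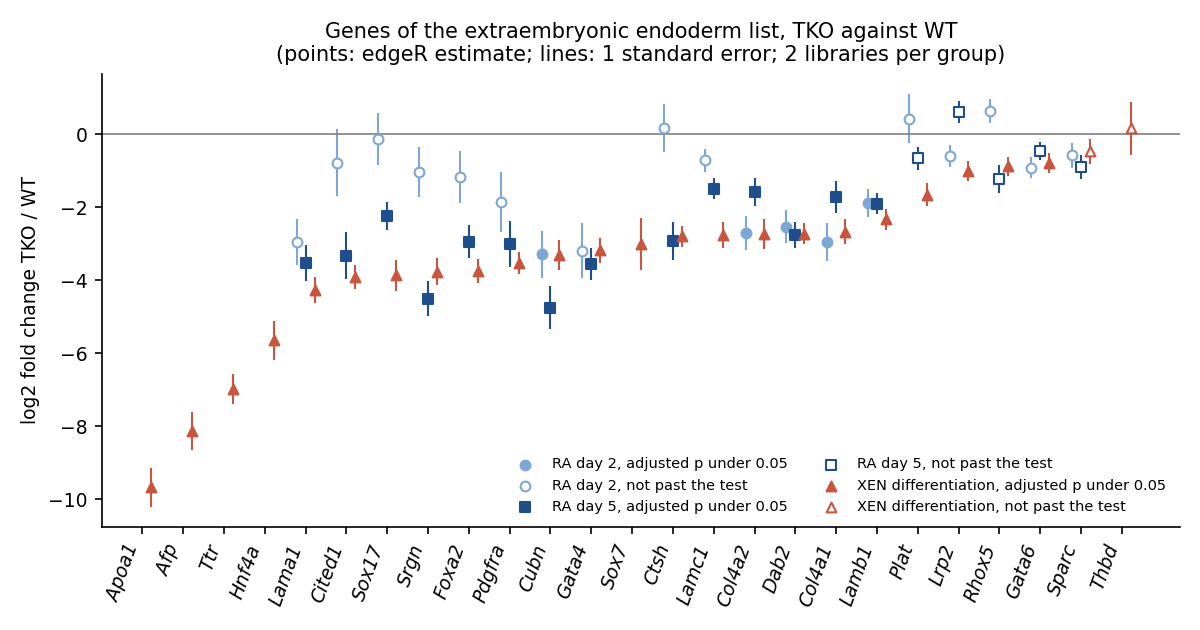
Log2 fold change of TKO over WT for genes of the extraembryonic endoderm list with counts in each group on RA day 2, RA day 5 and in XEN differentiation. Points are edgeR estimates of 2 against 2 libraries, bars are 1 standard error, and filled points have an adjusted p under 0.05, such as Cubn on day 5 at −4.76.

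From day 2 to day 5 both genotypes lost pluripotency RNA and gained muscle and mesenchyme RNA, which asks whether differentiation proceeds in each line. In WT the smooth muscle actin Acta2 rose at least 1180-fold from 0 counts, the growth factor Igf2 rose from 2.15 to 469 CPM (log2 7.44 ± 0.47, adjusted p 6.56e-11, 2 against 2 libraries, edgeR quasi-likelihood test, Benjamini-Hochberg), and the hindbrain gene Hoxb1 fell from 219 to 2.74 (−6.48 ± 0.48, 1.99e-09). The basement membrane gene Sparc rose in WT (2.85 ± 0.35, 1.99e-06). In TKO Acta2 rose 6460-fold (counting interval 1160 to 255000), Dppa5a fell (−6.13 ± 0.39, 4.93e-11) and Col4a2 rose (4.48 ± 0.48, 3.57e-06). In WT 1159 genes rose and 695 fell, 1854 in all. The WT total was 902 and 1060 without day 2 WT libraries 1 and 2, and 1131 and 1147 without day 5 WT libraries 1 and 2 (edgeR quasi-likelihood test, Benjamini-Hochberg). In TKO 2011 rose and 1694 fell, 3705 in all, with 1412 without day 2 TKO library 1 and 2068 without day 5 TKO library 1.

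Pluripotency and epiblast genes fell and mesenchyme genes rose in each line between the days. Pluripotency genes counted 1 rising and 11 falling of 19 in WT, or 1 and 13 over the list alone (camera adjusted p 1.34e-08, estimated correlation 0.021), and 2 and 14 in TKO, or 2 and 15 (1.18e-08, 0.0272). Epiblast genes counted 0 and 7 of 9 in WT (1.63e-08, 0.021) and 1 and 6 in TKO (1.24e-05, 0.0272). Mesenchyme genes counted 7 and 0 of 11 in WT, 8 over the list alone (6.22e-07, 0.021), and 7 and 0 in TKO (1.24e-05, 0.0272). Imprinted genes counted 10 and 3 of 22 in WT, 12 and 3 over the list alone (0.000113, 0.0291), and 11 and 3 in TKO, 16 and 3 over the list alone (0.000439, 0.0387). Extraembryonic endoderm genes counted 16 rising and 2 falling of 21 in WT with a median of 2.31 (camera adjusted p 3.8e-08, lost with an estimated correlation at adjusted p 0.0885). In TKO they counted 8 and 1, or 9 and 1 over the list alone, with a median of 1.22 (camera 0.0406, estimated correlation adjusted p 0.437). Hox genes counted 2 and 9 of 23 in WT (camera 0.00074, estimated correlation adjusted p 0.0885) and 7 and 6 in TKO (camera 0.833). The p53 targets counted 5 and 0 of 12 in WT, 8 over the list alone (0.00024, estimated correlation 0.0345), and cell cycle genes 0 and 7 of 16 in WT, 0 and 9 over the list alone (0.00233, lost at 0.105), and 0 and 10 in TKO, 0 and 11 over the list alone (3.39e-05, lost at 0.0984).

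The effect of TET loss on Dnmt3l turned from higher on day 2 to lower on day 5, and the interaction of genotype and day tests such differences. Dnmt3l stood at 342 CPM in WT and 935 in TKO on day 2, and at 92.8 and 14.3 on day 5 (interaction log2 −4.16 ± 0.44, adjusted p 1.59e-05, 2 libraries in each of 4 groups, edgeR quasi-likelihood test, Benjamini-Hochberg). Dppa5a, a pluripotency RNA-binding gene, fell in the interaction (−2.95, 0.00154). Both kept their calls in every setting. Hoxc5 rose in it (3.18 ± 0.56, 0.00863), but not without day 2 WT library 1 (2.88). In total 9 genes rose and 25 fell, 34 in all by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. The total was 9 without day 2 WT library 1, 18 without WT library 2, 11 without day 2 TKO library 1, 65 without day 2 TKO library 2, 8 without day 5 WT library 1 and 17 without day 5 TKO library 2. Without day 5 TKO library 1, 18 rose and 16 fell. Hox genes counted 3 rising and 0 falling of 23, or 9 and 0 over the list alone, with a median of 1.41 (camera adjusted p 6.9e-07, estimated correlation adjusted p 0.209). Extraembryonic endoderm genes counted 0 and 0 of 21, or 1 and 4 over the list alone (camera 0.00048, estimated correlation 0.371, fry 0.186).

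In XEN differentiation RNA of some endoderm genes was far lower in TKO than in WT cells. The comparison asks whether extraembryonic endoderm can form without TET enzymes. The fetal albumin gene Afp fell from 162 ± 49.2 to 0.385 ± 0.545 CPM (log2 −8.13 ± 0.52, adjusted p 2.31e-07, 2 against 2 libraries, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). Ttr fell from 257 ± 2.74 to 2.28 ± 1.18 (−6.99 ± 0.40, 3e-08) and Rbp4, which carries retinol, from 423 to 5.41 (−6.38 ± 0.39, 5.23e-08). The lipoprotein gene Apoa1 was 931-fold lower (counting interval 318 to 4520, adjusted p 3e-08). Rising genes included the matrix gene Efemp1 (6.85 ± 1.74 to 134 ± 2.69 CPM, 4.30 ± 0.33, 4.35e-07), the imprinted signal adaptor Grb10 (8.06 to 163, 4.29 ± 0.40, 5.15e-06), Dmd (5.12 ± 0.48, 3.74e-06) and Ecm1 (4.22, 8.48e-07). Of 13423 genes 1344 rose and 1426 fell, 2770 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. There were 1795 without TKO library 1.

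Of 26 extraembryonic endoderm genes in XEN 0 rose and 24 fell, with a median of −3.10 (camera adjusted p 6.52e-19, estimated correlation adjusted p 0.143). Gata4 fell by 3.18, Sox17 by 3.87 and Foxa2 by 3.76 on the log2 scale. Of 21 Hox genes 17 rose and 0 fell, or 19 over the list alone, with a median of 2.19 (camera adjusted p 2.14e-13, estimated correlation 0.143). Hoxc5 rose (4.93 ± 0.51, adjusted p 6.12e-06, edgeR quasi-likelihood test, Benjamini-Hochberg) and so did Hoxa5 (3.25 ± 0.33, 5e-06). Of 16 cell cycle genes 12 fell, or 13 over the list alone, with the mitotic kinase Plk1 lower (−2.93 ± 0.33, 1.89e-05; camera adjusted p 4.63e-07, estimated correlation 0.383, fry 0.0644). The RA response list counted 7 rising and 2 falling of 14, or 9 and 2 over the list alone, with the retinal reductase gene Dhrs3 higher (2.33, 3.41e-05) and the retinol uptake receptor gene Stra6 lower (−2.35, 4.58e-05; camera 0.00473, estimated correlation 0.383, fry 0.0644). Neural crest genes counted 4 and 0 of 8, or 6 and 0 over the list alone (camera 0.00139, estimated correlation 0.383). Mesoderm counted 5 and 1 of 10, or 6 and 1 over the list alone, with the endothelial receptor gene Kdr higher (3.71; camera 0.00473, estimated correlation 0.383, fry 0.0749). Mesenchyme counted 5 and 2 of 11, with Dcn higher (3.15) and Col1a2 lower (−3.82; camera 0.029, estimated correlation 0.423, fry 0.0644).

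The remaining XEN lists did not pass camera. Methylation genes counted 0 rising and 3 falling of 12 (adjusted p 0.0861), Dnmt3b (−2.80), Uhrf1 (−2.07) and Dnmt1 (−1.31). PRC2 genes counted 0 and 3 of 13, or 0 and 5 over the list alone (0.0697), among them Epop (−2.95). Pluripotency counted 3 and 6 of 13 (0.219), with Lin28a lower (−4.34) and Dppa2 higher (3.15). Neural counted 4 and 1 of 10 (0.0854), trophoblast 3 and 6 of 9 (0.134), germline 3 and 2 of 6 (0.371), imprinted 8 and 3 of 21 (0.298), Wnt 2 and 1 of 5 (0.81), p53 2 and 0 of 12 (0.319) and stress 0 and 4 of 12 (0.219). Epiblast (4 genes), blood (4), TET (3) and 2-cell-like genes (0) were too few to test.

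The fall of endoderm RNA went with a fall in the share of endoderm-like cells. In XEN differentiation, 223 of 329 and 263 of 424 WT cells lay in extraembryonic endoderm-like clusters (67.8%, interval 62.6 to 72.6, and 62%, 57.3 to 66.5). In TKO there were 12 of 479 and 14 of 285 (2.5%, 1.4 to 4.3, and 4.9%, 2.9 to 8.1). On RA day 5, 85 of 307 and 65 of 214 WT cells lay there (27.7%, 23 to 32.9, and 30.4%, 24.6 to 36.8), against 9 of 268 and 2 of 253 in TKO (3.4%, 1.8 to 6.3, and 0.8%, 0.2 to 2.8). On day 2 the WT shares were 5.8% (3.5 to 9.4) and 10.4% (6.6 to 16) and the TKO shares 0% (upper limit 1.2) and 1.9% (0.6 to 5.3). Differences between group means were 61.2 points in XEN, 26.9 on day 5 and 7.2 on day 2. Clustered without the listed and marker genes they were 60.7, 28.8 and 6 points. Cells of a 2-cell-like cluster, uncertain for Zscan4 copies, made up 40.8% (35.4 to 46.3) and 27.8% (21.5 to 35.1) of day 2 TKO libraries and 4.1% and 4.3% of WT. At resolution 0.3 the cluster of that name took in most day 2 cells, with 55.7% and 74.7% of TKO and 65.4% and 67.7% of WT. Mesenchyme-like cells made up 21.7% and 27.4% of XEN TKO and 0% (upper limit 1.2) and 0.9% of WT. Their cluster had 2.43 times the counts per cell of the others, and their share depends on the clustering, with 48.9% and 71.9% of TKO at resolution 0.3 and no cluster of that name at resolution 1.0.

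**Figure D2:**
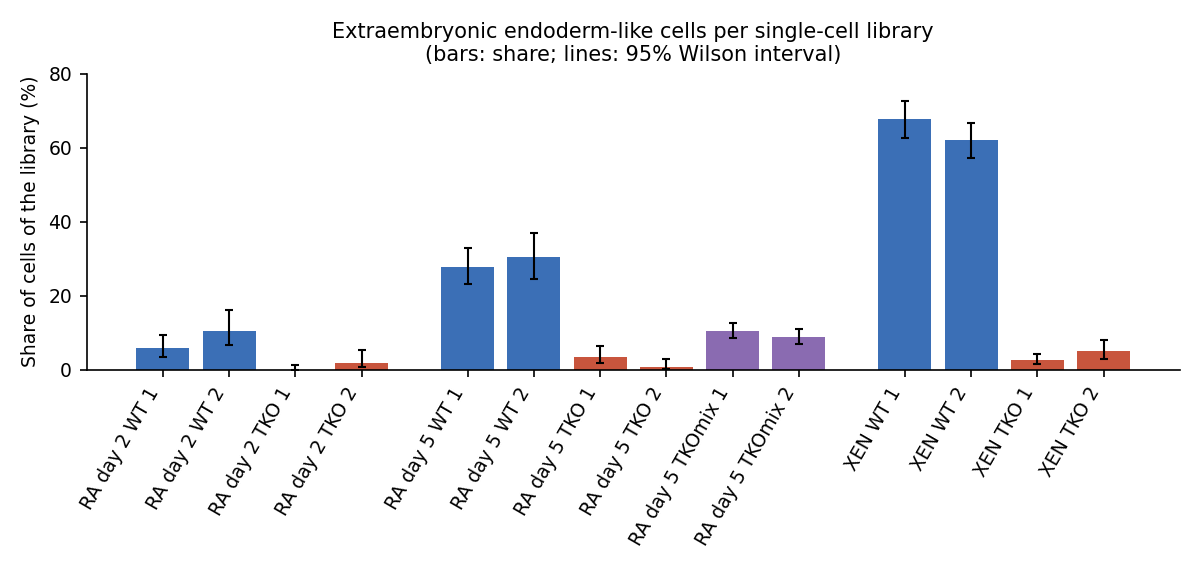
Share of cells (percent, vertical axis) in the extraembryonic endoderm-like class for each single-cell library on the horizontal axis. Bars are shares and lines 95% Wilson intervals, from 0% in day 2 TKO library 1 to 67.8% in XEN WT library 1.

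TKOmix libraries on day 5 held more endoderm RNA than libraries of TKO cells cultured alone, and this comparison asks whether WT neighbours restore differentiation. The laminin genes Lamb1 (log2 1.79 ± 0.29, adjusted p 1.5e-05) and Lamc1 (1.78) rose, as did the endoderm factor Sox17 (2.11 ± 0.37, 4.76e-05; 2 against 2 libraries, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). The membrane protein gene Plp2 rose from 9.70 to 659 CPM (6.09 ± 0.45, 4.37e-09) and Agap2 fell from 643 to 4.90 (−7.00 ± 0.41, 1.04e-12). In TKOmix 81.6% and 82.1% of values were whole numbers (within 0.005), against 58.8 to 70.7% in the other RA libraries, so the comparison joins co-culture with a difference between libraries. The labels do not say whether the mixed cells were sorted, so WT cells among them, endoderm-like ones included, are not ruled out. Eno1 rose by 5.82, but its reads are uncertain, as its near-identical copy Eno1b went from 3954 and 3825 to 856 and 387 CPM. Of 21 endoderm genes 15 rose and 0 fell, over all genes and over the list alone, with a median of 1.71 (camera adjusted p 0.000439, estimated correlation adjusted p 0.786). Hox genes counted 7 rising and 2 falling, imprinted 7 and 5, germline 5 and 0, neural 0 and 4 and cell cycle 5 and 2, and no other list passed camera (adjusted p 0.479 or more). Endoderm-like cells made up 10.5% (8.6 to 12.7) and 8.7% (6.9 to 11) of TKOmix. They lay in a cluster of their own, with 0 TKOmix cells in the cluster that held the endoderm-like cells of TKO. A mesenchyme-like cluster held 81.8% and 81.5% of TKOmix cells, but no cluster took that name at resolution 1.0. Clustered without TKOmix, 75.4% and 62.1% of day 5 TKO cells were mesenchyme-like, and of 11 mesenchyme genes 2 rose and 2 fell between TKOmix and TKO (camera adjusted p 0.931). In total 2967 genes rose and 3183 fell, 6150 in all.

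Against WT, TKOmix cells had less Ttr (log2 −5.52 ± 0.64, adjusted p 2.11e-07), Cubn (−2.89 ± 0.43, 3.48e-05) and Srgn (−2.14 ± 0.35, 1.97e-05) and more Hoxa5 (2.35 ± 0.27, 8.84e-08) and Axin2 (3.11 ± 0.40, 5.06e-07; 2 against 2 libraries, edgeR quasi-likelihood test, Benjamini-Hochberg), which asks how far the co-cultured cells stay from WT. The pluripotency factor Pou5f1 was 99.1-fold lower (counting interval 26 to 842). Of 23 Hox genes 13 rose and 1 fell, or 14 and 1 over the list alone (camera adjusted p 0.0333, estimated correlation adjusted p 0.604). Of 21 endoderm genes 2 rose and 10 fell (camera 0.262), and of 9 Wnt targets 6 rose and 0 fell (camera 0.0972). In total 3337 genes rose and 3537 fell, 6874 in all. RLE scaling moved the median of all genes from 0.055 to 0.139. Here too the whole-value shares of the libraries differ (81.6 and 82.1% in TKOmix). Among genes with at least 99% whole values (within 0.005) 36.6% were called against TKO and 44.2% against WT, and 5.6% between TKO and WT.

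On day 2 H3K27ac, which marks active regulatory elements, was lower in TKO cells at some regions near Hox, neural and RA response genes. It was higher at 18 of 32 regions near 2-cell-like genes. Some of these genes have near-identical copies, so their regions are uncertain and need not be independent. How reads map among the copies was not checked. The comparison asks where enhancer activity depends on TET enzymes. The region at the Hoxc cluster (15, 102827838 to 102906903) fell by 0.91 ± 0.157 (adjusted p 1.01e-06, 2 against 2 libraries, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). Regions at Tshz1 (18, 84233230 to 84263510, −1.25 ± 0.164, 1.41e-11), Pax6 (2, 105513726 to 105522073, −1.04, 2.73e-06) and the RA-binding gene Crabp2 (3, 87758888 to 87766251, −1.04, 5.35e-07) fell. Regions at Tdgf1 (9, 110837722 to 110857529, 0.98 ± 0.17, 1.07e-06) and Dnmt3l (10, 77505273 to 77528912, 0.86 ± 0.164, 1.4e-05) rose, as did Tdpoz3 (3, 93613892 to 93630331, 1.89 ± 0.172, 1.29e-24), which is uncertain among its copies. The splicing gene Cwc22 lay in a region that rose from 108 and 105 to 878 and 1030 CPM (2, 77725000 to 77789823, 3.17 ± 0.168, 2.33e-74). More copies of this segment in the TKO line were not ruled out, so this rise need not be enhancer activity. Of all 51404 regions near a TSS 3267 were higher and 1777 lower, and no list was tested against that share. Regions near 2-cell-like genes counted 18 higher and 0 lower of 32, Hox 1 and 5 of 24, neural 1 and 7 of 43, RA response 1 and 8 of 47, pluripotency 9 and 2 of 55, epiblast 6 and 3 of 38, imprinted 4 and 8 of 58 and extraembryonic endoderm 4 and 3 of 56. PRC2 regions counted 5 and 1 of 32, germline 4 and 0 of 39, p53 4 and 0 of 28, TET 1 and 4 of 13, methylation genes 2 and 2 of 33, mesenchyme 2 and 2 of 33, mesoderm 1 and 2 of 48, Wnt 2 and 0 of 46, cell cycle 1 and 0 of 37, neural crest 0 and 1 of 29, and trophoblast, blood and stress 0 and 0 of 34, 31 and 25.

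Of the TET genes on day 2, the Tet3 region 6, 83341198 to 83397674, fell (log2 −0.76, adjusted p 0.000148, edgeR quasi-likelihood test, Benjamini-Hochberg). Of 201404 regions 14750 were higher and 7176 lower, 21926 in all. Scaled by the total of all bins, 11576 were higher and 10096 lower, so the higher share was 53.4% in place of 67.3%. The total was 10084 without WT library 1, 8772 without WT library 2 and 9459 without TKO library 2. Within 1 kb of a TSS 1082 rose and 670 fell of 16322 regions, and farther away 13668 and 6506 of 185082.

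On day 5 H3K27ac was lower in TKO at 17 of 56 regions near endoderm genes and higher at some regions near Hox, mesoderm and Wnt genes, which follows the day 2 question to a later stage. The region at the laminin gene Lama1 (17, 68030006 to 68098029) fell from 238 and 259 to 142 and 140 CPM (log2 −0.82 ± 0.161, adjusted p 5.45e-05, 2 against 2 libraries, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). A region at Srgn (10, 61980491 to 61997728) fell by 0.82 ± 0.169 (0.000153). Regions at Hoxb9 (11, 96111432 to 96126709, 1.05 ± 0.171, 4.17e-07), Cdx1, which activates Hox genes (18, 61192872 to 61196499, 1.39 ± 0.214, 5.96e-08), Tcf7 (11, 52094453 to 52098492, 1.31 ± 0.20, 4.66e-08) and Grb10 (11, 11935673 to 11938386, 1.90 ± 0.232, 7.69e-13) rose. Of all 51404 regions near a TSS 3534 were higher and 1212 lower, and no list was tested against that share. Extraembryonic endoderm regions counted 1 higher and 17 lower of 56, Hox 6 and 0 of 24, mesoderm 11 and 2 of 48, Wnt 8 and 0 of 46, epiblast 7 and 0 of 38 and germline 9 and 1 of 39. Neural counted 4 and 0 of 43, neural crest 4 and 0 of 29, p53 4 and 0 of 28, RA response 5 and 5 of 47, imprinted 3 and 5 of 58, blood 1 and 4 of 31, pluripotency 4 and 1 of 55, PRC2 2 and 3 of 32, methylation genes 3 and 0 of 33, 2-cell-like 4 and 0 of 32, mesenchyme 3 and 2 of 33, stress 3 and 0 of 25, cell cycle 3 and 0 of 37, TET 1 and 0 of 13 and trophoblast 1 and 2 of 34. In all 7222 regions were higher and 5637 lower, 12859. The balance turned to more lower than higher regions without WT library 1 and, separately, without TKO library 2. It turned to 5948 higher and 6293 lower for peaks in at least 2 libraries and 6329 and 6886 for peaks of higher score. With only the libraries of the day it was 6071 and 6643. Scaled by the total of all bins it was 8714 and 4696. Within 1 kb of a TSS 2172 rose and 380 fell of 16322 regions, and farther away 5050 and 5257 of 185082. The total was 4032 without WT library 1 and 3689 without TKO library 2. The interaction with day held for 8185 regions, 3449 higher and 4736 lower, a test added after the data were seen. Scaled by the total of all bins this turned to 5684 higher and 2971 lower. It also turned to more higher than lower regions without day 2 TKO library 2 and, separately, without day 5 WT library 2. It held for 2521 without day 2 WT library 2.

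**Figure D3:**
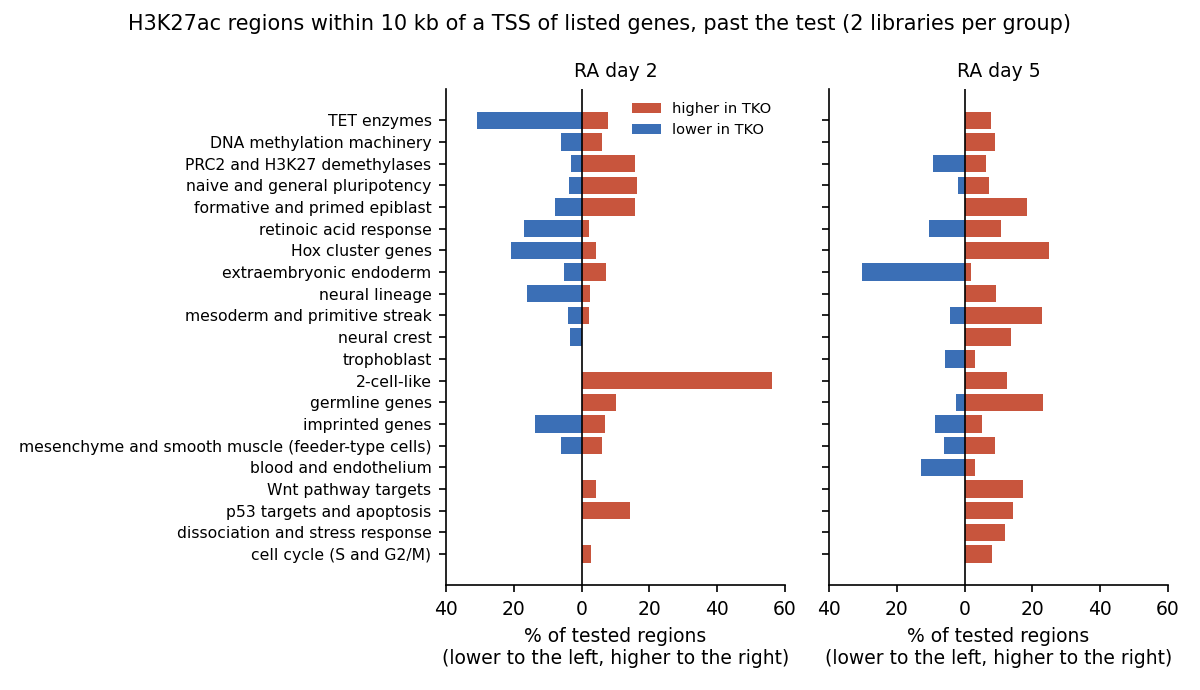
Share of tested H3K27ac regions within 10 kb of a TSS of each gene list (vertical axis) that were higher (right, percent) or lower (left, percent) in TKO on RA days 2 and 5. Bars are regions past the edgeR test of 2 against 2 libraries, such as 18 higher of 32 for the 2-cell-like list on day 2. Some genes of that list have near-identical copies, so its regions are uncertain.

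DNA methylation away from promoters was lower in TKO than in WT cells on day 2 and higher on day 5, and this comparison asks whether the loss of TET enzymes raises methylation of enhancers. Outside peaks, the day 2 levels were 67.88% and 68.13% in WT and 58.11% and 56.53% in TKO. The day 5 levels were 68.2% and 69.98% in WT and 72.5% and 73.21% in TKO. In peaks over 1 kb from a TSS they were 58.95% and 59.56% against 56.12% and 51.41% on day 2, and 64.03% and 63.62% against 67.89% and 68.18% on day 5. Near a TSS they stayed at 2.98 to 5.56% in every library. Over all calls, which depend on how many fall near promoters, day 2 levels were 46.43% and 47.61% against 45.75% and 38.06%. Day 5 levels over all calls were 52.89% and 50.74% against 50.57% and 50.93%, so TKO was not higher there. In all peaks they were 35.84% and 38.18% against 39.84% and 31.38% on day 2. On day 5 they were 42.51% and 40.04% against 39.9% and 42.17%. Levels over all calls and in peaks also depend on a few regions with very many reads. The region 2, 98506408 to 98507697 held 2224701 and 2758441 calls in WT against 4815969 and 4366363 in TKO on day 2. On day 5 it held 682189 and 510275 against 1686358 and 2375224. A region at Cubn (2, 13401003 to 13433470) lay 17.7 points lower on day 2 (69% and 66.6% to 51.2% and 49.1%, adjusted p 0.000297, moderated quasi-binomial test with limma's squeezeVar, Benjamini-Hochberg, 2 against 2 libraries). The same region lay 15.1 points higher on day 5 (46.3% and 48.4% to 60.8% and 63.7%, 0.000123; interaction 32.8 points, 7.11e-05). The RA and Hox partner gene Meis2 (2, 115867623 to 115881316) lay lower by 14.5 points on day 2 (0.000869), with an interaction of 23.6 points (0.000491). On day 5 the protease gene Plat (8, 23864747 to 23883351) gained 13.5 points (0.000156), Cyp26a1 (19, 37768736 to 37780085) gained 7.7 (0.000727) and Cdx1 lost 20.7 (0.00277). The median difference over all tested regions was −7.915 points on day 2, 4.289 on day 5 and 12.629 in the interaction. Values of single regions were not corrected for this shared shift.

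On day 2, 163 regions were more and 8693 less methylated in TKO of 134788, 8856 in all by the moderated quasi-binomial test with limma's squeezeVar. On day 5, 4333 were more and 473 less methylated of 147547, 4806 in all. The interaction held for 11511 of 125714, 11465 of them higher on day 5. No region passed when limma was fitted to the level itself, where the smallest adjusted p was 0.0771, 0.308 and 0.088, and 34763, 16354 and 35825 regions had an unadjusted p under 0.05. So every region named here was lost under that model. Without 1 library, the day 2 count went down to 2072 (WT library 1), the day 5 count to 888 (WT library 1) and the interaction to 3152 (day 5 WT library 1). A minimum difference of 20 points left 2435, 858 and 5953. Of all tested regions near a TSS 75 were higher and 2840 lower of 39931 on day 2, 1656 and 397 of 42255 on day 5, and 3728 and 38 of 38217 in the interaction, and no list was tested against these shares. Regions near extraembryonic endoderm genes counted 0 higher and 11 lower of 45 on day 2 and 9 and 0 of 50 on day 5, and pluripotency 0 and 9 of 48 on day 2. RA response regions counted 0 and 6 of 41 on day 2 and 8 and 1 of 41 on day 5, imprinted 1 and 6 of 49 and 12 and 0 of 51, and Hox 0 and 0 of 22 and 5 and 1 of 21. The interaction held for 13 of 39 RA response, 12 of 45 extraembryonic endoderm and 10 of 48 imprinted regions, all higher.

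**Figure D4:**
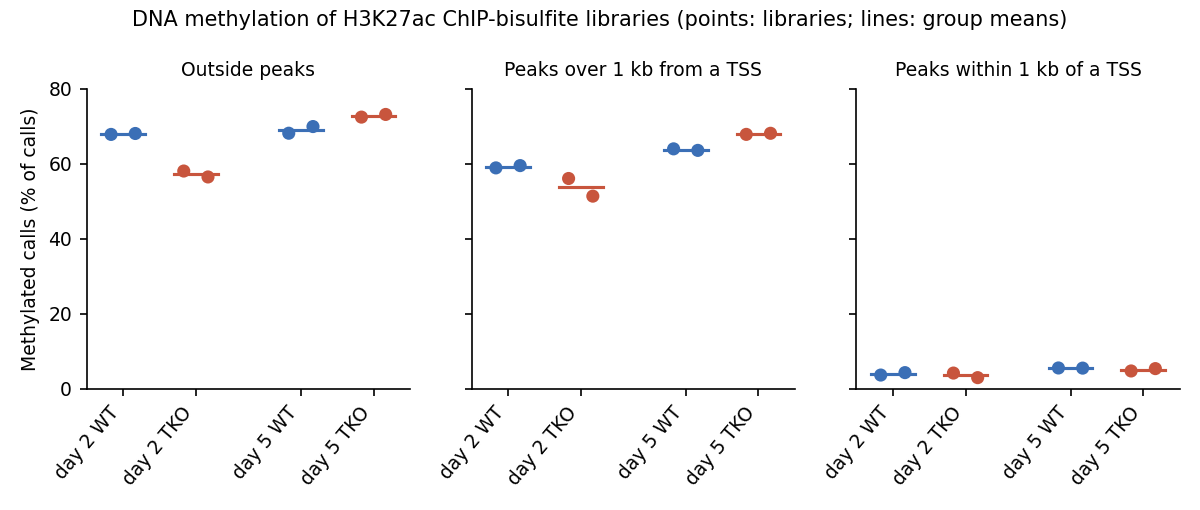
Share of cytosine calls that were methylated (percent, vertical axis) in each H3K27ac bisulfite library, outside peaks, in peaks over 1 kb from a TSS and in peaks near a TSS. Points are libraries and lines group means, such as 67.88% and 68.13% in day 2 WT outside peaks.

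In ESCs, promoter H3K27me3 of developmental genes was lower in TKO than in WT, and this comparison asks whether TET enzymes sustain Polycomb marking. It has 1 library per group, no test and no replicate check. Reads at Hoxa2 went from 880 to 330 (log2 ratio −1.37 ± 0.09, counting error), at Gata6 from 696 to 276 (−1.28 ± 0.10), at Cyp26a1 from 590 to 259 (−1.13 ± 0.11) and at Meis2 from 364 to 91 (−1.86 ± 0.17). Tet3 itself stood at −1.07. The median of the 6519 promoters with most signal was −0.42 (quartiles −0.79 and 0.04), with 879 at least 2-fold lower and 116 higher. A window wider than 2 kb left 305 in all and a 10 times larger pseudocount 216, in place of 995. List medians were −0.97 for Hox (percentile 1.22), −0.97 for neural crest (3.76), −0.95 for neural (0.09), −0.82 for RA response (0.04), −0.82 for mesoderm (6.98), −0.66 for trophoblast (8.44) and −0.62 for stress (2.15). They were −0.52 for Wnt (17.9), −0.50 for extraembryonic endoderm (13.3), −0.35 for epiblast (22.4), −0.31 for imprinted (51), −0.21 for germline (90.4) and −0.15 for blood (65). They were −0.04 for pluripotency (20.6), 0.06 for p53 (37.4), 0.12 for PRC2 (60.8), 0.14 for methylation genes (52.9), 0.17 for cell cycle (60.9), 0.25 for mesenchyme (93) and 0.41 for 2-cell-like genes (98.25). Against random lists matched on the WT signal instead, RA response (0.46) and neural (0.7) stayed low, while Hox (4.44) and stress (5.5) came inside the middle 95%. The TKO library was flat around promoters, with a mean of 4.993 reads per bin within 2 kb of a TSS and 4.883 beyond 8 kb, against 6.043 and 4.523 in WT. At least 2-fold lower were 11 of 24 Hox, 8 of 24 neural and 6 of 18 RA response promoters. Higher promoters were few, led by Pigm (17 to 390 reads, 3.84) and Cwc22 (27 to 366, 3.31). For Cwc22 a higher copy number in the TKO line was not ruled out.

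H3K27me3 of TKOmix ESCs lay close to WT, with a median of −0.07 (quartiles −0.30 and 0.17; 40 promoters at least 2-fold higher and 52 lower), again in 1 library with no replicate check. This comparison asks whether WT neighbours restore the mark. RA response genes stood at −0.29 (percentile 1.29), Hox at −0.29 (4.59) and neural at −0.24 (9.53). Meis2 stayed low (−1.35, 107 reads), the promoter of Bmp4 was higher (87 to 245 reads, 1.72), and Pigm (281 reads, 3.70) and Cwc22 (165, 2.53) stayed high. Without rescaling for depth the median was −0.41 and 286 promoters differed 2-fold in place of 92. H3K4me3, the mark of active promoters, differed little, with a median of 0.02 in TKO (7 promoters at least 2-fold higher, 1 lower) and −0.08 in TKOmix (6 and 1). Cwc22 had 1702 H3K4me3 reads in WT, 15333 in TKO and 10064 in TKOmix (3.23 and 3.14). Its copy number stays open here as well. Zfp985 (1.59 and 1.71) and Acp5 (1.13 and 0.91) were higher and Dynlt1b lower (−1.19 and −1.01).

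**Figure D5:**
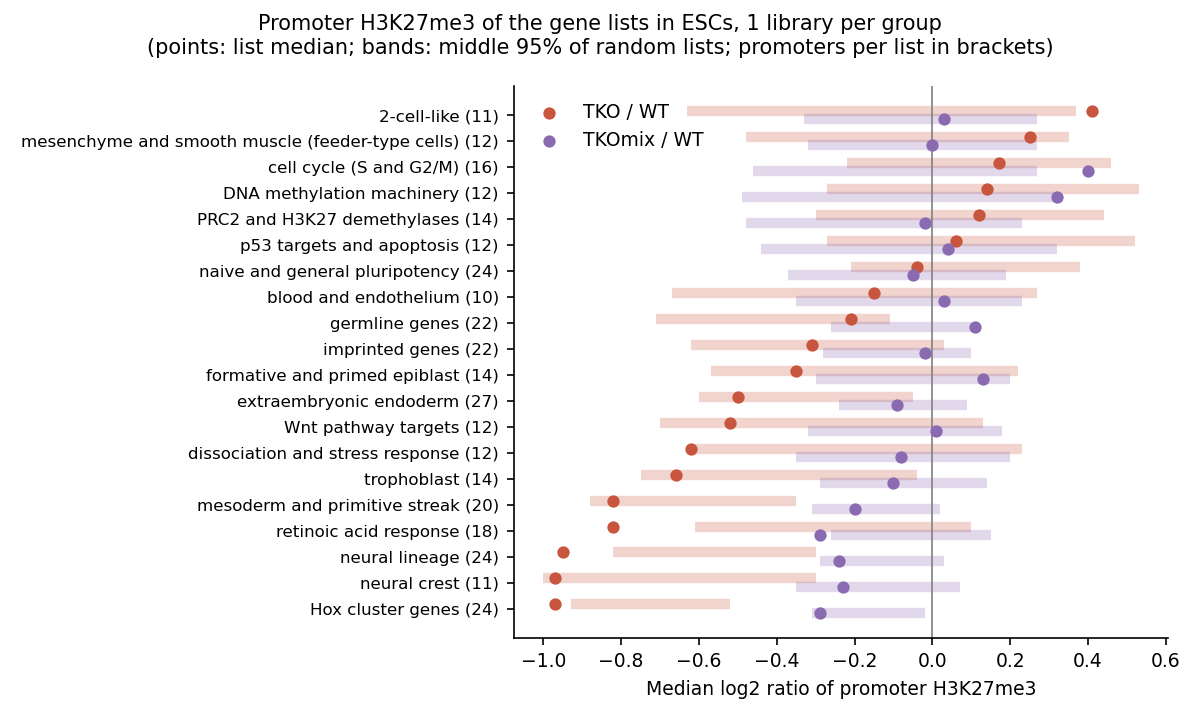
Median log2 ratio of promoter H3K27me3 (horizontal axis) for each gene list (vertical axis) in TKO and TKOmix ESCs over WT, 1 library each. Points are list medians, such as −0.97 for Hox in TKO, and bands the middle 95% of 10000 random lists of like signal.

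Bulk RNA of ESCs asks which genes TET loss affects before differentiation, with 1 library per genotype, no test and no replicate check. TKO cells had more of the 2-cell-stage genes Obox6 (12 to 615 counts, log2 ratio 4.66) and Trim43a (4 to 542, 4.92), both from families of near-identical copies and so uncertain. They had more Lamb1 (1.38), Col4a1 (1.29), Lrp2 (7.33 to 39.3 CPM, 2.27), Krt8 (2.10), Meis2 (1.99) and Igf2 (2.69), and less of the replication histone genes Hist1h2ah (1248 to 0 counts) and Hist1h2ao (3759 to 35, −5.96), which have near-identical copies and are uncertain. They also had less Apoa2 (269 to 3 counts, −3.71), Olig2 (−3.00), Stra8 (−2.02) and Peg3 (−2.09). The polycomb partner Jarid2 (1.02) and the H3K27 demethylase Kdm6b (1.18) were higher. Of 10518 genes 721 were at least 2-fold higher and 243 lower, with a median of 0.16. TMM scaling moved the median to −0.05 and gave 473 and 371, and TPM moved it to 0.01 and gave 442 and 274. List medians were 0.96 for extraembryonic endoderm (percentile 100), 1.02 for trophoblast (99.35), 0.50 for p53 (99.2), 0.59 for epiblast (98.75), 0.30 for pluripotency (94.85), 0.58 for germline (94.7) and 0.38 for PRC2 (94.7). They were 0.14 for Wnt (43.2), 0.10 for neural (36.8), 0.07 for stress (34.1), 0.10 for methylation genes (32.9), 0.06 for cell cycle (18.2), −0.78 for RA response (0.03, 6 members) and −0.29 for imprinted genes (0.03, 18 members). Of the 8 endoderm genes measured in ESCs 4 were at least 2-fold higher in TKO.

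Genes with lower promoter H3K27me3 in TKO ESCs were compared with other genes of high signal and with all genes, which asks whether the mark's loss reaches expression. In XEN, 66 rose and 33 fell of 206 such genes, with a median of 0.56 (camera p 0.0862, adjusted p 0.328). On RA day 5 13 rose and 8 fell of 197 (adjusted p 0.404), and on day 2 2 rose and 0 fell (adjusted p 0.963). Against genes of high signal (1777 in RA) camera called 0 sets, while 3 sets had an unadjusted p under 0.05. It called 2 with sets of 1000 genes, 2 with a 5 kb window and 4 against all genes. The former 2 and 2 were the set with higher H3K27me3, lower than the background from day 2 to day 5 in WT (camera adjusted p 0.0063 and 0.00968) and in TKO (0.000898 and 0.00968). The 4 were the set with lower H3K27me3, which was higher in TKO than WT in XEN (camera adjusted p 0.00179) and on day 5 (0.0456), and rose from day 2 to day 5 in WT (6.38e-06) and in TKO (1.21e-06). In bulk RNA of ESCs, 82 genes with lower H3K27me3 had a median of 0.56 (percentile 99.96; 0.33 and 91.52 with a 5 kb window, inside the middle 95%), and 20 with higher H3K27me3 a median of −0.13 (3.74). Genes near less methylated regions on day 2 counted 15 rising and 12 falling of 2143 (camera adjusted p 0.929), and genes near more methylated regions on day 5 counted 35 and 66 of 1420 (0.608). Camera called 0 of these methylation sets in any setting, and 0 sets had an unadjusted p under 0.05.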

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

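The interactions of methylation and of RNA were planned, while that of H3K27ac and the tests of explanations in this part were chosen after the results had been seen.

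DNA methylation of 11511 regions differed between TKO and WT in a way that changed from day 2 to day 5. The median change over all tested regions was 12.629 points, so much of this was a shift shared by most regions. Regions such as that at Cubn were less methylated in TKO on day 2 and more methylated on day 5. TET enzymes oxidise methylcytosine, and whether the loss of that activity gave the lower methylation on day 2 was not tested. The levels were read from H3K27ac chromatin, so they need not hold for the whole genome. An exchange of WT and TKO on 1 day was tested with the reads around Cwc22. They were at least 2.85 higher in TKO on the log2 scale on each day. That run was chosen because its regions were higher in TKO on both days, so its direction was partly fixed by the choice. The Cwc22 promoter also carried more H3K4me3 and H3K27me3 in TKO in the separate ESC libraries, which argues against an exchange on 1 day. Incomplete conversion in the day 2 WT libraries was tested at promoters, where the higher of their levels was 4.32% and a failure of 23.3% would be needed, so it is excluded. A difference in cell types between the cultures was not tested. The count falls to 0 when limma is fitted to the level.

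Of single genes, 34 had a TKO difference that changed between the days, among them Dnmt3l, which was higher in TKO on day 2 and lower on day 5. Dnmt3l helps to set new methylation, and its RNA moved against the methylation of the same day. H3K27ac of 8185 regions had a TKO difference that changed between the days.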

How the results depend on the processing

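Alternatives chosen after the data were seen are the fits without the deepest cell or the co-cultured libraries, thinned XEN libraries, clustering without TKOmix or without listed and marker genes, the gene sets against all genes and the H3K27ac interaction. Of 229 headline values under other settings 74 moved, counts by more than 1.5-fold and cell shares by more than their spread. The share of higher calls crossed 50%, with a move of over 10 points, in RNA on day 2 (25.9% without WT library 1, 58% with all), in RNA on day 5 (35.8% without WT library 1, 51.2% with all), in the RNA interaction (52.9% without day 5 TKO library 1, 26.5% with all), in H3K27ac on day 5 (42.2% without WT library 1, 56.2% with all) and in the H3K27ac interaction (65.7% by the total of all bins, 42.1% by TMM). Of 7349 settings of named single-cell genes 6850 kept call and value, 441 were weaker, 18 stronger and 40 moved. Of 2660 settings of named regions 2167 stayed and 493 were weaker. Of 560 settings of named genes with 1 library per group 174 moved and 386 stayed. Of 390 settings of list medians with 1 library per group 78 moved and 312 stayed. Of 51 settings of other cell shares 7 moved and 44 stayed. The causes of these changes were not tested. Leaving out 1 library gave 19 to 227 genes on day 2 (88 with all libraries), 148 to 330 on day 5 (527), 4474 to 6121 for TKOmix against TKO (6150), 5016 to 6973 for TKOmix against WT (6874), 902 to 1147 for WT day 5 against day 2 (1854), 1412 to 3547 for TKO day 5 against day 2 (3705), 8 to 65 for the interaction (34) and 1795 to 3270 for XEN (2770). It gave 8772 to 21814 H3K27ac regions on day 2 (21926), 3689 to 9552 on day 5 (12859) and 2521 to 10097 in the interaction (8185). It gave 2072 to 11811 methylated regions on day 2 (8856), 888 to 1985 on day 5 (4806) and 3152 to 15496 in the interaction (11511), and a difference of endoderm-like shares in XEN of 58.3 to 64.1 points (61.2). With no filter on low counts there were 232 genes on day 2 and, rounded, 1.0e2 in the interaction, of which 50 rose and 52 fell. Without the deepest cell, which held 14.71% of the counts of day 2 TKO library 1, 77 genes were called on day 2 (41 rose, 36 fell). DESeq2 called 333 genes on day 5. The interaction held for 55 genes with only the libraries of the groups compared, and for 55 without the co-cultured libraries. A difference of at least 0.2 in methylation left 2435 regions on day 2, 858 on day 5 and 5953 in the interaction. A fit of the libraries of 1 day gave 3579 regions on day 2 and 7827 on day 5. With limma on the level 0 regions passed on day 2, 0 on day 5 and 0 in the interaction. With an estimated correlation 9 of 47 list calls held, all of them between days. The share difference in XEN was 56.4 points at resolution 1.0 and 66.4 with at least 2000 counts per cell. For H3K27me3 in TKO a wider window left 305 promoters and a 10 times larger pseudocount 216 (of 995). For TKOmix these were 21 and 8, and 286 with no rescaling (of 92). For H3K4me3 in TKOmix no rescaling gave 180 promoters (of 7). Bulk RNA gave 552 genes with a pseudocount of 5 and 1637 with a minimum of 10 counts (of 964). Sets by H3K27me3 gave 2 calls with 1000 genes, 2 with a 5 kb window and 4 against all genes (of 0). The replicate numbers were not used to pair the samples in the main tests. Correlations of same-number deviations were −0.17 to 0.186 in RA, 0.319 in XEN, −0.01 to 0.159 for H3K27ac and −0.005 to 0.013 for methylation. A shared part of same-numbered samples is not ruled out in XEN, where a replicate block gave 3820 genes (2770 without it), nor for H3K27ac. With a replicate block there were 93 genes on day 2 and 20285 H3K27ac regions on day 5, and 14148 in the H3K27ac interaction, while the other counts stayed within 1.5-fold. Other aligners, peak callers and doublet callers were not run.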

Other observations

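Written before their results were seen were the tests of shared reads, sequencing depth, cell share and copy number, and the others were written after.

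Around Cwc22 on chromosome 2, 8 neighbouring regions from 77707579 to 77865247 gained H3K27ac in TKO cells on both days, and the Cwc22 promoter gained H3K27me3 (log2 3.31) and H3K4me3 (3.23) in ESCs. An active and a repressive mark rose together at 1 locus. A neighbouring region (2, 77808196 to 77833810) rose by 3.78 ± 0.184 on the log2 scale on day 2. A higher copy number of the segment in the TKO line could raise all marks. The 140 bins of the run outside every peak stood at 0.24 on day 2 and −0.05 on day 5 in TKO over WT on the log2 scale (lowest pair of libraries −0.13), which met the bound written beforehand against this explanation. That bound was wrong by design, because the peaks include those of TKO, so a bin raised in TKO was no longer outside a peak. The bins left held 1.26 reads each against 7.04 in the flanks, and 59 held none in any library. The 633 of 788 bins outside the peaks of WT, counted after the result was seen, stood at 3.24 and 2.89. Bins of the run within peaks stood at 3.15 and 2.92, and flanking bins outside peaks at −0.04 and −0.12. More copies would give such an even rise, as would a broad gain of the mark, so the explanation stays open.

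In XEN differentiation the factors Gata4, Sox17 and Foxa2 stood at 0.46, 0.19 and −0.36 in TKO against WT within the endoderm-like cells, while Ttr (−2.44), Afp and Apoa1 stayed lower there by the edgeR test (adjusted p 0.0498, 0.00261 and 0.0019). Within that class 3 of 23 called genes fell. The median of the list's called members was −3.24 over all cells and 0.13 within the class. The markers that name the class all belong to the list, so a small change within it was partly built in. A mean of 3.7% of TKO cells lay in the class, and 20 of 8446 genes were called there. The value within the class therefore does not settle whether fewer endoderm-like cells explain the fall of the list. Outside the class the median was −2.4 (Gata4 −2.86, Sox17 −4.03, Foxa2 −3.96), so this part stays open. Outside the class most WT cells lay in another cluster (57 and 121 cells) than most TKO cells, and RNA carried over from the endoderm-like cells of the WT libraries was not measured. Afp, Apoa1 and Ttr were chosen because they passed the test within the class, so the bound written for them afterwards was met by choice. They were past the edgeR test adjusted over all 8446 genes there, though Ttr only just and with few TKO cells. This argues against a lower share of the whole class as the only cause of their fall, but does not exclude it. A loss of 1 kind of endoderm-like cell is not excluded for them, since the cluster they marked held 25 and 54 WT cells and 0 and 1 TKO cells. Thinning all libraries to the smallest total kept 1.017 of the fold change, which met the bound written beforehand against sequencing depth. Thinning the summed counts keeps their proportions, so little change was likely whatever the cause. It also leaves the counts per cell as they were, with medians of 15039 and 9874 in TKO and 4855 and 5653 in WT. Sequencing depth is therefore not excluded.

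At 6150 calls against TKO, many genes separated the co-cultured day 5 libraries from the others. Reads shared between near-identical genes are excluded as the main cause, because 36.6% of genes with at least 99% whole values were still called. A difference between library batches remains open, since at least 81.6% of their values were whole numbers (within 0.005) against at most 70.7% in the other RA libraries (70.4 to 79% in XEN), and no measure here parts batch from co-culture.

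Promoter H3K27me3 was lower in TKO ESCs and close to WT after co-culture. WT cells in the TKOmix cultures would explain the return, and H3K27me3 promoters imply a WT share of 58.6% (879 lower in TKO) or 49.2% (116 higher). Those promoters were chosen by the ratio of the same TKO and WT libraries, so error in that ratio alone tends to place TKOmix between them. Such shares therefore do not by themselves point to WT cells. H3K4me3 promoters that differ between the lines imply 1.68%, which excludes WT cells as the source in the H3K4me3 library, though only 8 promoters carry that value and the H3K27me3 library may differ. Pigm, Cwc22 and Zfp872 imply 9.91%, 46.8% and 10.6%. Weaker enrichment in the TKO library does not by itself account for 4 of 20 lists outside those matched on WT signal, of which 2 lay below (RA response and neural) and 2 above (2-cell-like and mesenchyme). Weaker enrichment remains open, also for the drop of the median.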
